A study of Bos taurus with 24 samples.

How the data were processed

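RNA was extracted from cultured subcutaneous pre-adipocytes of Holstein cows and sequenced in 24 libraries: CON, PA, OA and MIX, each with 3 cows at day 4 (cows 4 to 6) and 3 other cows at day 7 (cows 1 to 3). Other doses, other mixtures and the PPARA antagonist arms of the study were not analysed here. Per the submitters' processing notes, FastQC 0.11, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used. The roles of these tools, the aligner, the genome build and the strand setting are not given in the sources used here.

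For day 4 the deposited table holds a raw count per gene and library. The authors also gave FPKM per gene and library, relative to a scaled library size rather than the sum of counts. The deposited day 4 table further holds the authors' log2 fold change for 6 comparisons, and the authors' p-value and adjusted p-value for each. For day 7 the deposited table holds FPKM alone. Per the file headers each table also gives the gene length in bases. Reads of day 7 were recovered from FPKM, gene length and the smallest step per library, and 100% were whole within 0.01. This was done after the data were examined, so a count test on these reads is used only as an alternative. The 2 tables hold 27570 genes with Ensembl cow gene identifiers, of which 26 have names turned into dates and were kept by identifier. Reads shared between near-identical genes, such as the CXCL chemokines, ACTA2 and ACTG2, or the ANXA8 family, could be split between them by the counting the authors used.

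The groups, comparisons, tests, 26 gene lists and the alternatives to the fits without cow as a block were fixed before the data were examined. The fits on recovered reads and the alternatives to the fits with the block were chosen afterwards. The lists hold 538 genes, of which 499 were found, 3 of them by an older symbol. DGAT2 and the mitochondrially encoded genes were not analysed here. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9, with seed 20 where draws were made. Day 4 counts were filtered with filterByExpr (13580 genes kept), scaled by TMM and tested with edgeR's quasi-likelihood test on 4 group means. A prior count of 2 was used only for log2 CPM, in the list tests, principal components and ratios within a cow. Day 7 FPKM were kept where at least 3 libraries reached 1 FPKM (12615 genes), put on the log2(FPKM + 1) scale and tested with limma-trend. The difference between days was tested with limma on 12132 genes in all 24 libraries. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05, and tests were two-sided. A difference is given as the mean of the first group minus the second, in log2.

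A fit with cow as a block, fixed in advance, is given throughout, since a cow number names the same animal in the 4 groups of a day. This pairing was checked: the deviations from the group mean correlated across genes at r = 0.757 to 0.912 for the 18 same-cow pairs of day 4 and 0.772 to 0.865 for those of day 7, against at most 0.04 and -0.31 for other pairs. Log2 differences and SE of single genes are from the fit with the block unless stated. FPKM are group means with SD. List medians and the numbers of members higher or lower are from the fit without the block.

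Lists were tested with camera from limma at a preset correlation of 0.01, with an estimated correlation, and with fry. No list held with an estimated correlation or with fry. Members were also adjusted over the list alone: 0 passed in every list without the block, and the counts given are from the fit with it. Genes were named by a fixed rule: the 10 with the largest change each way among those past the threshold with a symbol, a mean of at least 2 FPKM in the higher group and the same direction in all 3 cows. Places left went to genes past the threshold only with the block, and 5 each way were allowed for comparisons of MIX with PA or OA and between days. Up to 4 members with the smallest p of each list that moved were added, together with a fixed set of lipid, PPAR, stress and inflammation genes. Genes outside this rule are said to have been chosen after their values were seen.

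The tests of OA against CON were tried on data simulated from the 12 libraries of each day. In OA, 100 genes were changed 1.5-fold and 100 were changed 2-fold, each by the same amount in every cow. The changed genes were drawn from those with at least 50 counts in every library, so recovery of lower genes was not tried. At day 4 edgeR with the block made 7 false calls among 197, and limma with the block 8 among 185. At day 7 (13658 genes) edgeR with the block made 16 false calls among 211 and limma with the block 10 among 193. Other alternatives were DESeq2, limma in place of edgeR, no filter, stricter filters (50 counts or 5 FPKM), a pseudocount of 0.1, robust fitting, only the compared groups, and leaving out each cow and each library. Group splits were counted over all 10 splits of 6 libraries or 50 drawn splits of 9. The floor for a gene at 0 is 3 counts of the library's total and, like the 95% limits, covers counting error only.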

Results

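Pre-adipocytes isolated from the subcutaneous adipose tissue of 6 Holstein cows were induced to differentiate in medium with troglitazone, a PPARG agonist. They were left without added fatty acid (CON) or given palmitic acid (PA, saturated), oleic acid (OA, monounsaturated) or a mixture of 60% PA and 40% OA (MIX), each at 300 µM in total. Cells of cows 4 to 6 received the fatty acids during induction and were collected at day 4. Cells of cows 1 to 3 received them after the induction phase and were collected at day 7. Each treatment at each day had 3 RNA-seq libraries, 1 per cow, giving 24 libraries. Total counts were 13509548 to 17071654 per library at day 4, and the reads recovered from the day 7 FPKM values were 14118798 to 24008811. At day 7 the CON libraries were the deepest on average, at 19358115 to 24008811 reads against 14118798 to 19859107 for PA. A gene without a read could have been present at up to 0.222 CPM at day 4 and 0.213 CPM at day 7 (3 counts per library, counting error only).

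The first question was what these cultures expressed. Fibroblast and stromal transcripts dominated: MMP2, COL1A1, THBS1, VIM, SPARC and DCN were among the 15 genes of day 4 with the highest FPKM. Library medians of the fixed preadipocyte and fibroblast marker list were 42.4 to 80.1 FPKM at day 4 and 29.6 to 73.4 at day 7. Of its 19 members, 14 averaged at least 1 FPKM at each day. DLK1 had no read in any library, and CD34 averaged 0.02 FPKM at day 4 and 0.37 at day 7. DPP4, PI16 and GATA3 averaged at most 0.051 FPKM at either day. The adipocyte marker list lay far lower, at medians of 0.489 to 1.54 FPKM at day 4 and 0.206 to 0.459 at day 7. ADIPOQ, the adipokine adiponectin, had 3 reads in all 24 libraries together and none in 22 of them. FABP4, the adipocyte fatty acid binding protein, averaged 30.3 ± 17.6 FPKM over the 12 libraries of day 4 and 0.41 ± 0.49 over the 12 of day 7. PPARG averaged 3.07 ± 1.64 and 0.23 ± 0.11 FPKM, LPL 0.88 and 0.46 FPKM, and PLIN1 1.85 and 1.05 FPKM. Other members of the list were higher: RBP4, the retinol carrier, averaged 44.8 ± 19.8 FPKM at day 4 and 69.7 ± 20.9 at day 7, PNPLA2, the triacylglycerol lipase of lipid droplets, 8.34 and 12.6, and ADIRF 6.80 and 2.64. Of its 18 members, 8 averaged at least 1 FPKM at day 4 and 6 at day 7. The 2 tables were normalised separately and came from different cows, so these levels were not tested between days. Smooth muscle and myofibroblast markers reached library medians of 13.6 to 200 FPKM at day 4 and 25.9 to 303 at day 7. Library medians were 0 to 0.0635 FPKM for the macrophage and leukocyte list, 0 to 0.0163 for the endothelial list and 0 to 0.0446 for the epithelial and mesothelial list. Single members lay higher, among them CD14 (6.02 FPKM at day 4 and 10.5 at day 7), CD68 (4.48 and 2.43), MSLN (1.20 and 6.06), UPK3B (1.82 and 1.28) and FLT1 at day 4 (1.92).

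**Figure D1:**
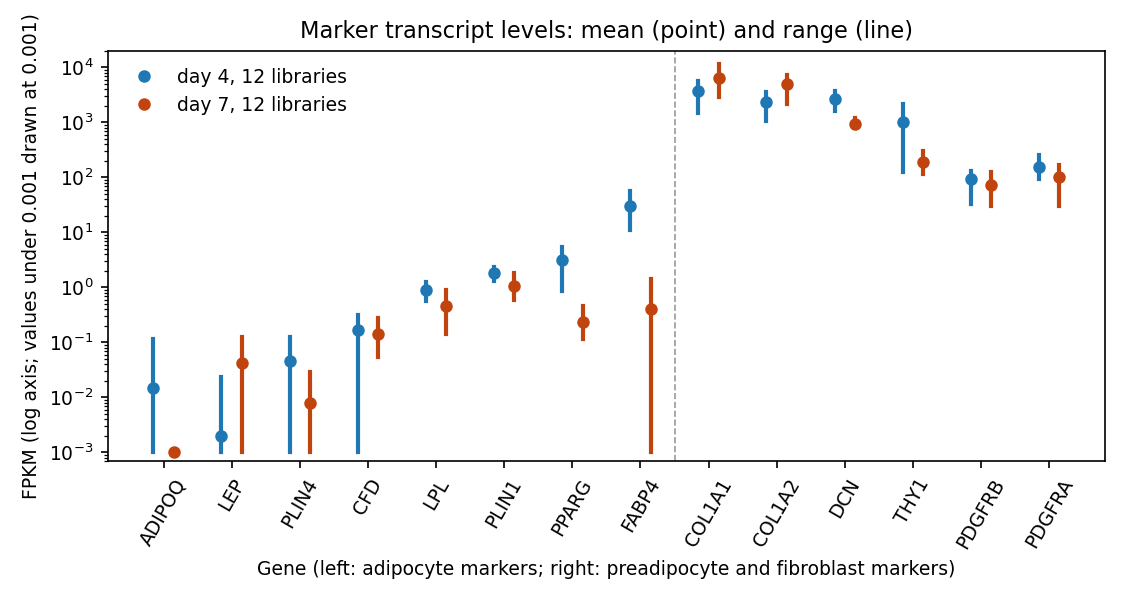
Mean FPKM (log axis) of marker genes over the 12 libraries of day 4 and the 12 libraries of day 7, with bars from the lowest to the highest library; the 2 days were normalised separately. FABP4 and PPARG lay lower in the day 7 table, and ADIPOQ was near 0 in both.

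Cows differed far more than treatments. Cow accounted for 84.8% of the sum of squares of log2 expression at day 4 and 81.5% at day 7, treatment for 5.16% and 6.44%. Random spread also adds to the treatment share, which was not tested against the residual. ACTG2, a smooth muscle actin, shows the spread between animals, at 143 ± 224 FPKM (SD, n = 3) in CON libraries of day 4. Without cow in the model, edgeR at day 4 and limma at day 7 called 0 genes in every comparison at an adjusted p of 0.05, and the values with cow as a block are therefore given beside each of these counts. In simulations of OA against CON at day 4 (13580 genes), edgeR without the block recovered 0 of 100 genes changed 1.5-fold and 0 of 100 changed 2-fold, and with the block 91 and 99. The changed genes had at least 50 counts in every library, so these values do not cover lower genes. Each was given the same change in every cow and drawn independently of other genes. Many genes were changed together, which makes adjustment over all genes easier to pass. Recovery in the real libraries can therefore be lower. In the authors' deposited table for day 4, 0 genes had an adjusted p under 0.05 in any of the 6 comparisons, and between 4 and 24 had a p under 0.05.

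**Figure D2:**
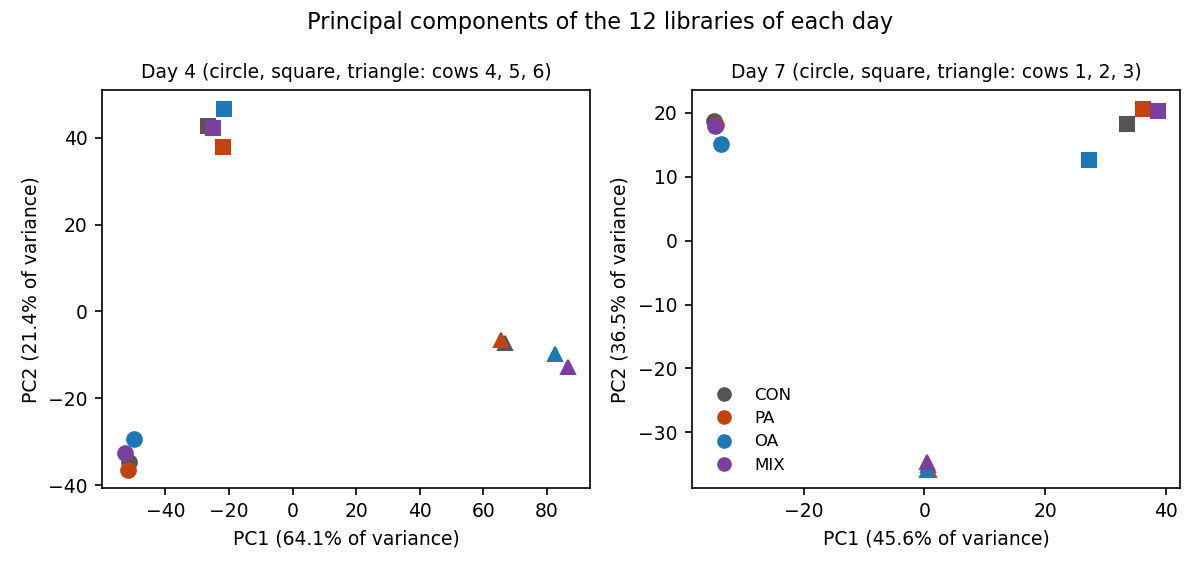
Principal components 1 and 2 of log2 expression at day 4 (64.1% and 21.4% of the variance) and day 7 (45.6% and 36.5%), 1 point per library, with cow and treatment marked. Libraries group by cow at both days.

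PA was compared with CON at day 4 to ask what the saturated fatty acid did during induction. Lipid-handling genes that respond to PPAR were higher in each cow without passing the test. PDK4, which inhibits pyruvate dehydrogenase, averaged 3.03 ± 0.97 FPKM with PA and 1.81 ± 0.52 without (SD, n = 3 each). ANGPTL4, an inhibitor of lipoprotein lipase, averaged 155 ± 106 and 128 ± 111 FPKM, and PLIN2, a lipid droplet coat protein, 504 ± 268 and 420 ± 267. All 3 were higher in 3 of 3 cows, with log2 differences of 0.73 ± 0.16 (SE), 0.40 ± 0.08 and 0.30 ± 0.08 in edgeR with cow as a block, but none passed adjustment over all genes (adjusted p 0.438, 0.438 and 0.726). CPT1A, the carnitine palmitoyltransferase of the mitochondrial outer membrane, differed by 0.16 ± 0.07 and DDIT4, a stress-induced inhibitor of mTORC1, by 0.30 ± 0.07 (adjusted p 0.443). IL6 differed by 0.50 ± 0.17, PPARG by 0.30 ± 0.13, CD36 by 0.30 ± 0.14 and SCD by 0.01 ± 0.11.

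The PPAR-responsive lipid genes rose as a list with PA at day 4: 15 of 18 members were higher, with a median log2 difference of 0.11 (camera with preset correlation, adjusted p = 0.0169, and 5.42e-06 with cow as a block). The call was lost with an estimated correlation (adjusted p = 0.722, and 0.163 with the block). Adjusted over the list alone, 3 members rose with the block, and 0 passed over all genes. With the block, camera also called the list of insulin signalling and glucose uptake (10 of 15 members higher, adjusted p = 0.0341, 0.408 with an estimated correlation) and the integrated stress and unfolded protein response (22 of 29 higher, adjusted p = 0.0341, 0.385 with an estimated correlation). Within the stress list DDIT3 differed by 0.15 ± 0.09 and MANF by -0.15 ± 0.08, neither passing the test. Over all 13580 genes edgeR called 0 without the block (15 at p under 0.05) and 0 with it (429 at p under 0.05).

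OA was compared with CON at day 4 to ask what the monounsaturated fatty acid did in the same cows. With cow as a block, 10 genes rose and 0 fell. Among them were inflammatory genes: IL6 went from 6.73 ± 3.61 to 14.2 ± 7.95 FPKM (log2 difference 1.07 ± 0.17, adjusted p = 0.00715), PTGS2, the inducible prostaglandin synthase, from 9.08 ± 3.13 to 15.4 ± 2.85 (0.78 ± 0.11, adjusted p = 0.00509), CXCL5 from 343 ± 330 to 503 ± 497 (0.53 ± 0.09) and CCL2 from 97.6 ± 77.1 to 131 ± 101 (0.43 ± 0.07, both adjusted p = 0.00899). Genes of lipid uptake and storage also rose: OLR1, a receptor for oxidised low-density lipoprotein, from 1.98 ± 0.37 to 4.60 ± 2.10 FPKM (1.17 ± 0.20, adjusted p = 0.0131), CD36, a fatty acid transporter, from 3.09 ± 2.11 to 4.96 ± 2.42 (0.77 ± 0.14, adjusted p = 0.0166) and PLIN2 from 420 ± 267 to 546 ± 247 (0.45 ± 0.08, adjusted p = 0.0131). The others were ACTG2 (0.59 ± 0.09, adjusted p = 0.00715), the aminopeptidase ANPEP (0.56 ± 0.10, adjusted p = 0.0194) and the WNT antagonist SFRP4 (0.31 ± 0.06, adjusted p = 0.0239). Each of the 10 was higher with OA in 3 of 3 cows. They were called in these same cow pairs, so this agreement is not separate support.

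**Figure D3:**
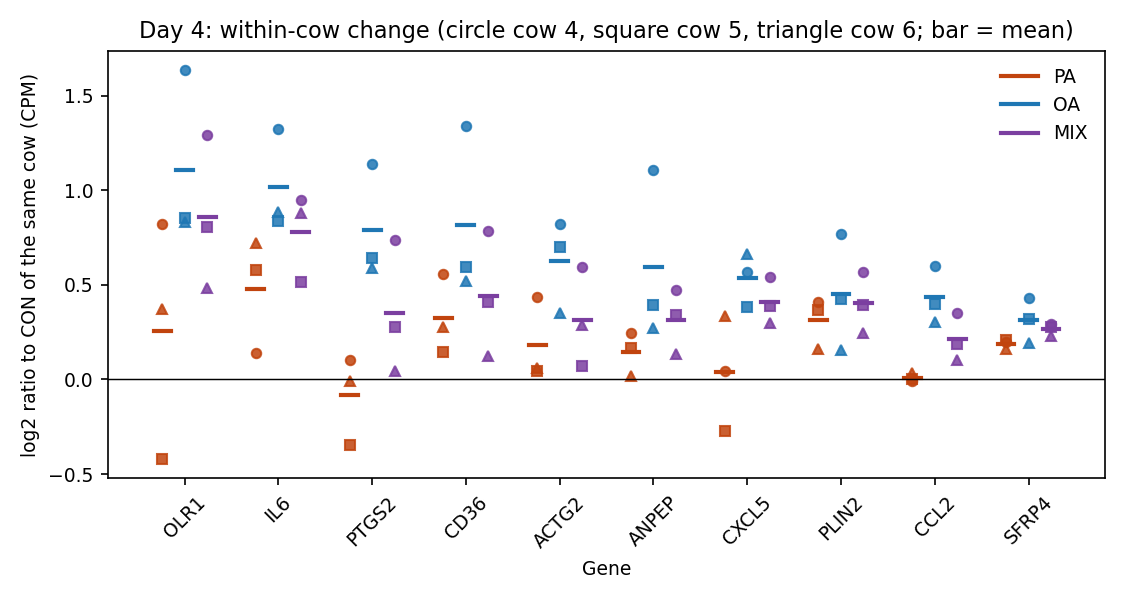
Log2 ratio of CPM to the CON library of the same cow (vertical axis) at day 4 for the 10 genes that rose with OA with cow as a block, 1 point per cow (4, 5 and 6) and a bar at the mean for PA, OA and MIX. All 30 OA points lie above 0, from 0.15 for PLIN2 in cow 6 to 1.64 for OLR1 in cow 4. The genes were called in these same cow pairs.

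The fixed lists gave the same genes a wider frame at day 4. Of 16 inflammation genes, 11 were higher with OA, with a median log2 difference of 0.27. The list rose by camera with preset correlation (adjusted p = 0.000126, and 4.23e-11 with the block) but not with an estimated correlation (adjusted p = 0.114, and 0.112 with the block). Adjusted over the list alone 8 members rose with the block, and 4 over all genes. Cholesterol synthesis rose with 21 of 24 members higher and a median of 0.13 (adjusted p = 2.42e-06; 0.114 with an estimated correlation). ACAT2 differed by 0.39 ± 0.09 and HMGCS1, the synthase that makes HMG-CoA, by 0.45 ± 0.12, neither past the threshold over all genes. Of the members, 2 rose when adjusted over the list alone with the block. The list median was 0.30 and 0.23 in cows 5 and 6 but -0.06 in cow 4. Proliferation genes rose with 23 of 28 members higher (adjusted p = 0.00149; 0.967 with an estimated correlation), among them MCM2 at 0.40 ± 0.10 and RRM2 at 0.48 ± 0.18, and 1 rose when adjusted over the list alone with the block. Smooth muscle and myofibroblast markers moved in the same libraries: 10 of 14 were higher, 8 rose when adjusted over the list alone with the block, and camera called the list only with the block (adjusted p = 3.46e-08, against 0.420 without it and 0.133 with the block and an estimated correlation). ACTA2, the alpha smooth muscle actin, differed by 0.48 ± 0.10 (adjusted p = 0.0620).

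PPAR-responsive lipid genes were called as a list with OA only with the block (10 of 18 higher, 2 risen over all genes, camera adjusted p = 0.00492, 0.285 with an estimated correlation). Other lists were also called higher only with the block. These were extracellular matrix (22 of 27 higher, adjusted p = 0.000108, 0.440 with an estimated correlation), oxidative stress (15 of 19, 0.000632, 0.285), the integrated stress and unfolded protein response (22 of 29, 0.00364, 0.300), preadipocyte and fibroblast markers (13 of 14, 0.0056, 0.383) and fatty acid uptake (8 of 11, 0.0056, 0.257). Fatty acid oxidation (19 of 27, 0.0341, 0.285), de novo lipogenesis and desaturation (12 of 18, 0.0341, 0.300; 1 when adjusted over the list alone with the block) and oxidative phosphorylation (25 of 30, 0.0389, 0.613) followed. The median was -0.0004 for extracellular matrix in cow 6 and -5.72e-05 for de novo lipogenesis and desaturation in cow 4. No single lipogenic gene passed over all genes with OA at day 4. FADS2, a desaturase, went from 6.62 ± 1.56 to 11.2 ± 5.34 FPKM (0.68 ± 0.15, adjusted p = 0.108), and SCD, the main desaturase of stearic acid, differed by 0.00 ± 0.11 and FASN by 0.15 ± 0.08. PDK4 (0.66 ± 0.16, adjusted p = 0.255) and ANGPTL4 (0.39 ± 0.08, adjusted p = 0.0878) were higher in 3 of 3 cows, as with PA, without passing. PPARA differed by 0.24 ± 0.19, PPARD by 0.04 ± 0.09 and PPARG by 0.10 ± 0.13. Without the block edgeR called 0 genes (24 at p under 0.05), and with the block the 10 calls became 33 by DESeq2, 0 by limma on log2(FPKM + 1) and 52 without the filter on low counts. The count depended on the animals and libraries used: it was 1 without cow 4, 0 without cow 5 and 76 without cow 6, 0 without the CON library of cow 4, 1 without the OA library of cow 4 and 4 without the OA library of cow 5. A fit without a cow also has fewer pairs, and whether a single animal set the count was not tested.

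MIX was compared with CON at day 4 to ask what both fatty acids did together. No gene passed the test. IL6 averaged 12.4 ± 7.44 FPKM with MIX and 6.73 ± 3.61 without (0.85 ± 0.17, adjusted p = 0.15), ANGPTL4 173 ± 151 and 128 ± 111 (0.42 ± 0.08, adjusted p = 0.15) and PLIN2 539 ± 288 and 420 ± 267 (0.39 ± 0.08, adjusted p = 0.15). OLR1 differed by 0.90 ± 0.21 (adjusted p = 0.395), CXCL5 by 0.41 ± 0.09 (adjusted p = 0.248), PDK4 by 0.57 ± 0.17 and PTGS2 by 0.34 ± 0.11, each higher in 3 of 3 cows. The inflammation list rose, with 12 of 16 members higher and a median of 0.20 (camera adjusted p = 0.0143, and 3.91e-06 with the block; 0.191 and 0.163 with an estimated correlation), and 4 members rose when adjusted over the list alone with the block. With the block, PPAR-responsive lipid genes also rose (13 of 18 higher, adjusted p = 0.000567, 0.257 with an estimated correlation; 3 when adjusted over the list alone with the block). So did smooth muscle and myofibroblast markers (11 of 14 higher, adjusted p = 0.00105, 0.285 with an estimated correlation). Oxidative phosphorylation (26 of 30 higher, adjusted p = 0.0015, 0.481 with an estimated correlation), glycolysis and hypoxia (15 of 23, 0.0326, 0.521), fatty acid uptake (9 of 11, 0.0454, 0.300) and preadipocyte and fibroblast markers (10 of 14, 0.0454, 0.479) were also called higher only with the block. EdgeR called 0 genes without the block (16 at p under 0.05) and 0 with it (473 at p under 0.05).

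OA and PA, given at the same dose to cells of the same cows, were compared to ask how an unsaturated and a saturated fatty acid differed. At day 4, 17 genes were higher and 13 lower with OA with cow as a block. PTGS2 was higher with OA (15.4 ± 2.85 against 8.60 ± 3.16 FPKM, 0.87 ± 0.11, adjusted p = 0.000991), as were CXCL5 (0.49 ± 0.09, adjusted p = 0.0108), CCL2 (0.43 ± 0.07, adjusted p = 0.00715) and PLAUR, the urokinase receptor (0.44 ± 0.08, adjusted p = 0.00715). The list of 16 inflammation genes had 15 members higher (median 0.27, camera adjusted p = 0.000655, and 9.54e-12 with the block; 0.114 and 0.112 with an estimated correlation), with 9 higher and 1 lower when adjusted over the list alone with the block. HMGCS1 was higher with OA (6.95 ± 2.87 against 4.48 ± 0.45 FPKM, 0.59 ± 0.12, adjusted p = 0.0285), and the cholesterol synthesis list was higher in 21 of 24 members (adjusted p = 1.66e-06, 0.114 with an estimated correlation; 4 when adjusted over the list alone with the block), with a median of -0.02 in cow 4. ABCA1, the cholesterol efflux transporter and an LXR target, was lower with OA (11.4 ± 8.73 against 18.6 ± 14.8 FPKM, -0.70 ± 0.12, adjusted p = 0.0108), and MYLIP, another LXR target, differed by -0.59 ± 0.14 without passing (adjusted p = 0.0795).

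Among genes with a symbol, the largest of the other differences called between OA and PA at day 4 were in WDR36 (1.10 ± 0.21, adjusted p = 0.0202) and, lower with OA, the phosphodiesterases PDE7B (-0.89 ± 0.17, adjusted p = 0.0202) and PDE3A (-0.78 ± 0.16, adjusted p = 0.0279). IGFBP5, an insulin-like growth factor binding protein, averaged 774 ± 140 FPKM with OA and 1041 ± 224 with PA (-0.42 ± 0.07, adjusted p = 0.00521). XIRP1, LIPG, KCNG1, TIMP3 and WISP1 were higher with OA by 0.44 to 0.55, and JADE1, KCNE4, ADAMTS5, SOX4, NOV and TSHZ1 were lower, at -0.47 to -0.42. Proliferation genes were higher in 25 of 28 members (camera adjusted p = 1.22e-05, 0.858 with an estimated correlation; 2 when adjusted over the list alone with the block), RRM2 by 0.78 ± 0.18 (adjusted p = 0.0771). Smooth muscle and myofibroblast markers moved with these groups, with 11 of 14 higher and ACTG2 by 0.43 ± 0.09 (adjusted p = 0.0466; list adjusted p = 1.49e-05 with the block, 0.519 without it, and 0.191 with the block and an estimated correlation). Other lists were called only with the block. Higher with OA were extracellular matrix (20 of 27, adjusted p = 0.0015, 0.481 with an estimated correlation) and oxidative stress (16 of 19, 0.00349, 0.300). Lower were insulin signalling and glucose uptake (11 of 15, 0.0260, 0.385) and LXR targets (6 of 9, 0.0397, 0.300).

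PDK4, ANGPTL4, CPT1A, PLIN2 and SCD did not pass between OA and PA at day 4. The 95% intervals of the log2 difference, not adjusted for the number of genes, were -0.39 to 0.25 for PDK4, -0.17 to 0.16 for ANGPTL4, -0.14 to 0.15 for CPT1A, -0.01 to 0.30 for PLIN2 and -0.24 to 0.22 for SCD. Over all genes edgeR called 0 without the block (23 at p under 0.05) and 30 with it, against 59 by DESeq2, 3 by limma and 117 without the filter. The count was 9 without cow 4, 0 without cow 5 and 202 without cow 6, and it moved to 12, 2 and 46 without the PA library of cow 4, 5 and 6 and to 12 and 3 without the OA library of cow 4 and 5.

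MIX was also set against each fatty acid alone at day 4. Against PA the inflammation list rose, with 15 of 16 members higher and a median of 0.17 (camera adjusted p = 0.0239, and 3.46e-08 with the block; 0.227 and 0.133 with an estimated correlation), 4 of them when adjusted over the list alone with the block. Against OA, cholesterol synthesis was lower in 22 of 24 members, with a median of -0.13 (adjusted p = 1.66e-06, 0.114 with an estimated correlation; 4 when adjusted over the list alone with the block). Against CON its mean of cow medians was -0.01 with MIX and 0.16 with OA, and in cow 4 the medians were -0.02 and -0.06. Proliferation was lower in 23 of 28 (adjusted p = 0.0143, 0.993 with an estimated correlation). OA against CON, OA against PA and MIX against OA share the OA libraries, so their results are not independent. Other lists were called only with the block. Against OA, extracellular matrix (21 of 27 lower, adjusted p = 0.00143, 0.481 with an estimated correlation), inflammation (11 of 16 lower, 0.00144, 0.285), smooth muscle markers (10 of 14 lower, 0.00283, 0.293) and lipogenesis (14 of 18 lower, 0.0355, 0.300) were lower. Interferon response genes were higher (13 of 16, 0.0389, 0.440). Against PA, proliferation (19 of 28 higher, adjusted p = 0.0326, 0.428 with an estimated correlation) and smooth muscle markers (13 of 14 higher, 0.0355, 0.385) were higher. Insulin signalling (10 of 15 lower, 0.0307, 0.385) and thermogenic genes (6 of 9 lower, 0.0335, 0.383) were lower. Against the weighted mean of PA and OA, inflammation was higher (13 of 16, adjusted p = 0.0211, 0.353 with an estimated correlation). Cholesterol synthesis (17 of 24 lower, 0.0335, 0.575) and thermogenic genes (7 of 9 lower, 0.0351, 0.385) were lower than that mean. No single gene was called by edgeR: 0 in MIX against PA without and with the block (16 and 443 at p under 0.05), 0 in MIX against OA (20 and 403) and 0 in MIX against the 60 to 40 weighted mean of PA and OA (16 and 257).

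At day 7, PA, OA and MIX were each compared with CON in cells of cows 1 to 3, on the log2(FPKM + 1) scale, which understates changes of low genes. With PA the lipid genes that led at day 4 lay near CON: ANGPTL4 averaged 39.4 ± 26.8 FPKM with PA and 40.1 ± 27.2 without (-0.02 ± 0.13), PLIN2 48.7 ± 16.9 and 50.2 ± 18.9 (-0.03 ± 0.07) and CPT1A 18.9 ± 6.84 and 18.3 ± 6.53 (0.04 ± 0.10). PDK4 was at 0.147 and 0.183 FPKM, under the filter. With the block only, extracellular matrix genes fell as a list with PA (26 of 27 lower, camera adjusted p = 0.000881, 0.781 with an estimated correlation; median 0.01 in cow 2), as did glycolysis and hypoxia genes (22 of 24 lower, adjusted p = 0.00122, 0.801 with an estimated correlation) and smooth muscle markers (11 of 11 lower, adjusted p = 0.0222, 0.759 with an estimated correlation). CTGF differed by -0.24 ± 0.09, TIMP2 by -0.14 ± 0.05 and GAPDH by -0.18 ± 0.08, none passing over all genes.

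With OA at day 7 sterol and fatty acid synthesis genes were lower. SCD averaged 35.0 ± 3.04 FPKM with OA and 63.1 ± 31.1 without (-0.68 ± 0.29, adjusted p = 0.521), SREBF1 35.5 ± 1.35 and 47.9 ± 7.92 (-0.41 ± 0.09, adjusted p = 0.424), SQLE, the squalene epoxidase, 17.0 ± 6.17 and 27.2 ± 16.0 (-0.49 ± 0.19) and IDI1 11.8 ± 4.15 and 18.9 ± 11.2 (-0.51 ± 0.18), without passing in limma. As lists, cholesterol synthesis fell (23 of 24 lower, median -0.29, camera adjusted p = 8.9e-05) and so did de novo lipogenesis and desaturation (13 of 17 lower, median -0.22, adjusted p = 0.00136), and nuclear genes of oxidative phosphorylation rose (26 of 30 higher, median 0.07, adjusted p = 0.00289). With an estimated correlation the adjusted p of each of these 3 lists was 0.996, and 0.759 with the block. Cow 1 went the other way, with a cholesterol list median of 0.19 against -0.57 in cow 2 and -0.43 in cow 3, and a lipogenesis median of 0.09 against -0.29 and -0.35. With the block proliferation genes rose too (26 of 28 higher, adjusted p = 0.000742, 0.759 with an estimated correlation; 1 when adjusted over the list alone with the block), TYMS by 0.30 ± 0.05 (adjusted p = 0.424). Glycolysis and hypoxia (23 of 24 higher, adjusted p = 0.0202, 0.918 with an estimated correlation) and fatty acid oxidation (22 of 26, 0.0366, 0.759) were also called higher only with the block. The glycolysis and hypoxia median was -0.13 in cow 3, against 0.23 and 0.20 in cows 1 and 2. PLIN2 differed by 0.22 ± 0.07 and ANGPTL4 by 0.39 ± 0.13, both higher in 3 of 3 cows without passing.

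With MIX at day 7 cholesterol synthesis fell as a list, with 24 of 24 members lower and none past the threshold (median -0.26, camera adjusted p = 1.6e-06). Its cow medians were 0.04, -0.36 and -0.41 in cows 1, 2 and 3. De novo lipogenesis and desaturation fell with 16 of 17 lower (median -0.13, adjusted p = 6.93e-05). LXR targets fell with 7 of 9 members lower (adjusted p = 0.0136), as did glycolysis and hypoxia genes with 23 of 24 (adjusted p = 0.00991), whose median was 0.01 in cow 1. The adjusted p of these lists was 0.996 with an estimated correlation, and 0.759 with the block. Preadipocyte and fibroblast markers were called lower only with the block (11 of 14, adjusted p = 0.0306, 0.759 with an estimated correlation). SREBF1 differed by -0.33 ± 0.09, FADS2 by -0.70 ± 0.29, ABCA1 by -0.49 ± 0.18 and DHCR7, the last enzyme of cholesterol synthesis, by -0.41 ± 0.17, without passing in limma. Limma called 0 genes against CON with PA, OA or MIX, without the block (58, 68 and 48 at p under 0.05) or with it (540, 1170 and 430). EdgeR on the recovered reads with the block also called 0. Without the filter on low values limma called 2 genes in each comparison, the microRNA gene bta-mir-544b-2 and an unnamed gene, with at most 1 read in a CON library and 0 elsewhere, named here after their values were seen.

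**Figure D4:**
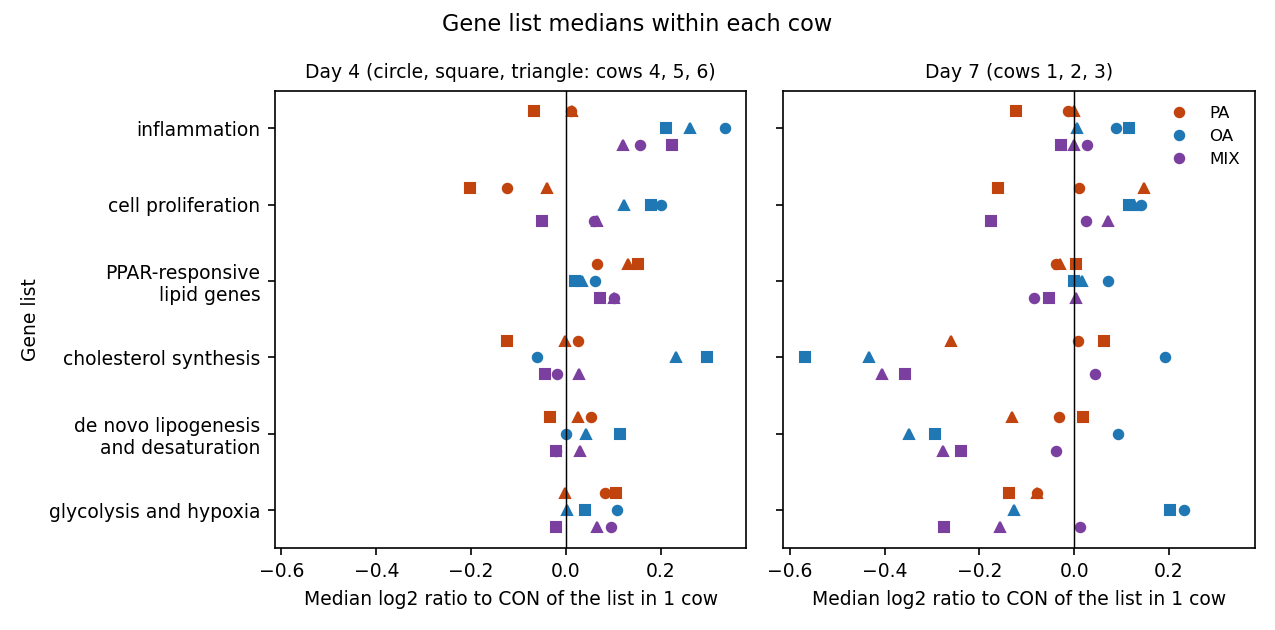
Median log2 ratio to CON of the same cow (horizontal axis) over the members of fixed gene lists (vertical axis), 1 point per cow, for PA, OA and MIX at day 4 (cows 4 to 6) and day 7 (cows 1 to 3). The ratios are of CPM at day 4 and of FPKM + 1 at day 7. With OA the inflammation medians at day 4 are above 0 in 3 of 3 cows, and the cholesterol medians at day 7 are 0.19, -0.57 and -0.43.

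OA against PA at day 7 gave 0 genes by limma without the block (87 at p under 0.05) and with it (1448 at p under 0.05, smallest adjusted p 0.169). EdgeR with the block on recovered reads found 7 genes higher with OA and 1 lower. MMP1, interstitial collagenase, averaged 7.17 ± 2.53 FPKM with OA and 2.84 ± 1.24 with PA (log2 difference of reads 1.39 ± 0.24, adjusted p = 0.0469), COL18A1 10.5 ± 8.86 and 4.49 ± 3.60 (1.14 ± 0.15, adjusted p = 0.0185) and ISG12(B), an interferon-stimulated gene, 19.2 ± 0.57 and 10.2 ± 1.57 (0.92 ± 0.13, adjusted p = 0.0195). MMP9 averaged 7.22 ± 12 and 1.69 ± 2.72 (1.94 ± 0.29, adjusted p = 0.0195). On the other scale, log2(FPKM + 1), which flattens values under 1 FPKM, MMP9 differed by 1.93, 0.07 and 0.29 in cows 1, 2 and 3. LPCAT1, an acyltransferase of phospholipid remodelling, averaged 53.6 ± 12.2 and 40.4 ± 11.0 (0.41 ± 0.06, adjusted p = 0.0195). TTC9 (0.68 ± 0.12) and GDF15 (0.60 ± 0.10) had an adjusted p of 0.0469, and the gene that was lower, FAM180A, is named here after its value was seen. The 8 calls became 0 in limma, 53 by DESeq2, 210 without the filter, and 1, 25 and 3 without cow 1, 2 and 3.

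By camera at day 7, cholesterol synthesis (22 of 24 lower, adjusted p = 0.00273) and de novo lipogenesis (11 of 17 lower, adjusted p = 0.0184) were lower with OA than with PA. Glycolysis and hypoxia (23 of 24 higher, adjusted p = 0.00428) and oxidative phosphorylation (25 of 30 higher, adjusted p = 0.0174) were higher, and with an estimated correlation each had an adjusted p of 0.996. Not every cow followed: in cow 1 the median was 0.14 for cholesterol synthesis and 0.11 for lipogenesis, in cow 3 -0.04 for glycolysis and hypoxia, and in cow 2 -0.01 for oxidative phosphorylation. Called higher with OA only with the block were extracellular matrix (25 of 27, adjusted p = 0.000742, 0.781 with an estimated correlation), proliferation (26 of 28, 0.00686, 0.781), smooth muscle markers (10 of 11, 0.0249, 0.759), inflammation (15 of 15, 0.0368, 0.759) and oxidative stress (15 of 19, 0.0482, 0.759). VEGFA differed by 0.38 ± 0.13 and CA9 by 0.60 ± 0.22, without passing. The 95% interval of the log2 difference, not adjusted for the number of genes, was -0.17 to 0.28 for CPT1A, 0.13 to 0.69 for ANGPTL4, 0.09 to 0.40 for PLIN2, -0.48 to -0.08 for DDIT3 and -1.20 to 0.10 for SCD.

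MIX lay below PA at day 7 in cholesterol synthesis (24 of 24 lower, camera adjusted p = 0.000131) and de novo lipogenesis (15 of 17 lower, adjusted p = 0.00289). It lay below OA in glycolysis and hypoxia (24 of 24 lower, adjusted p = 0.000131), oxidative phosphorylation (25 of 30 lower, adjusted p = 0.00852) and proliferation (26 of 28 lower, adjusted p = 0.0142; 2 when adjusted over the list alone with the block). Below the weighted mean of PA and OA it had cholesterol synthesis (23 of 24 lower, adjusted p = 0.0187) and glycolysis and hypoxia (22 of 24 lower, adjusted p = 0.0192). With an estimated correlation each of these lists had an adjusted p of 0.996. The median went the other way for cholesterol synthesis against PA in cow 1 (0.03) and for oxidative phosphorylation against OA in cow 2 (0.02). Only with the block, MIX was called above PA in extracellular matrix (24 of 27, adjusted p = 0.000881, 0.781 with an estimated correlation) and below PA in LXR targets (7 of 9, 0.0198, 0.759). Under the same condition it lay below OA in fatty acid oxidation (20 of 26, 0.0295, 0.759). It was likewise called below the weighted mean in proliferation (24 of 28, adjusted p = 0.00358, 0.781 with an estimated correlation), lipogenesis (15 of 17, 0.0267, 0.781) and LXR targets (7 of 9, 0.0457, 0.759). Limma called 0 genes in MIX against PA, OA and the weighted mean, without the block (62, 70 and 53 at p under 0.05) and with it (494, 1313 and 604). EdgeR on recovered reads with the block called 2 in MIX against OA, both lower with MIX: COL18A1 (-1.04 ± 0.15) and ANXA8L1 (-0.77 ± 0.11, both adjusted p = 0.0274).

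The days were compared to ask whether a fatty acid moved the same genes in both settings. Across 12134 genes, which are not independent replicates, the log2 differences from CON at day 4 and day 7 correlated at r = -0.06 for PA (Spearman's rho -0.07), 0.10 for OA (rho 0.12) and -0.01 for MIX (rho -0.06). Of the 10 genes that rose with OA at day 4, 9 were testable at day 7 and all 9 lay above CON there, with a median of 0.14. These genes share cows and CON libraries and are not independent, so no test is given. Over all genes 55.6% had the same sign at both days. Of the 30 genes called between OA and PA at day 4, 18 of 29 testable kept their sign at day 7, against 54.2% of all genes. Limma called 0 genes whose difference from CON changed between days, with PA, OA or MIX, without the block (23, 21 and 22 at p under 0.05 of 12132 genes) and with it (563, 666 and 539).

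OA and PA share their CON libraries, so their differences from CON must correlate. Across genes r was 0.437 at day 4 and 0.357 at day 7, against 0.501 at both days in 100 simulations of unchanged groups, and the covariance minus the simulated value was -0.00258 and -0.00323. With cow as a block 0 genes rose with both at day 4, among 0 called with PA and 10 with OA. Of those 10, IL6 differed by 0.50 ± 0.17 and PLIN2 by 0.30 ± 0.08 with PA, and CCL2 by 0.01 ± 0.07.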

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

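The tests of depth, missed genes, leukocyte reads, single cows, shared cows and the totals and thinned medians of the inflammation list below were chosen after the result was seen, as was the exact permutation of cow medians between days.

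Gene lists whose difference from CON changed between day 4 and day 7 were singled out by camera on the interaction with cow as a block, and all of those below lay lower at day 7 than at day 4. No list held with an estimated correlation. With OA the lists called by camera were cholesterol synthesis (adjusted p = 4.13e-13), de novo lipogenesis and desaturation (7.28e-06), smooth muscle and myofibroblast markers (2.31e-05), triacylglycerol synthesis and lipid droplets (0.00155) and the integrated stress and unfolded protein response (0.0270). The permutation p was 0.1 for smooth muscle markers and triacylglycerol synthesis, 0.2 for cholesterol synthesis, 0.3 for lipogenesis and 0.4 for the stress response. With PA camera called glycolysis and hypoxia (0.000250), extracellular matrix (0.00282), smooth muscle markers (0.0254), PPAR-responsive lipid genes (0.0270), triacylglycerol synthesis and lipid droplets (0.0270) and LXR targets (0.0437). The permutation p was 0.2 for triacylglycerol synthesis, 0.3 for extracellular matrix and LXR targets, and 0.1 for the others. With MIX camera called glycolysis and hypoxia (6.00e-07), cholesterol synthesis (2.21e-05), de novo lipogenesis (0.000744), smooth muscle markers (0.00230), LXR targets (0.00282), preadipocyte and fibroblast markers (0.00743), PPAR-responsive lipid genes (0.00896), oxidative phosphorylation (0.0270) and inflammation (0.0270). The permutation p was 0.2 for glycolysis and hypoxia and smooth muscle markers, 0.3 for oxidative phosphorylation, 0.4 for cholesterol synthesis and 0.1 for the others.

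Cholesterol synthesis genes were higher with OA at day 4 and lower at day 7. The cow medians were -0.06, 0.30 and 0.23 for cows 4, 5 and 6 and 0.19, -0.57 and -0.43 for cows 1, 2 and 3. An exact permutation test of these medians between days gave p = 0.2, where 0.1 is the smallest possible. It sets log2 CPM of day 4 against log2(FPKM + 1) of day 7, which understates changes of low genes. A single cow does not set the direction, which stayed without each of the 6 cows in turn. After quantile normalization the interaction stayed called by camera from limma (p = 1.09e-14, preset correlation). Camera compares the list with all other genes, and a shift of a whole library moves both alike. This check therefore cannot decide on scaling of the libraries. Day, animals and the start of treatment cannot be told apart, because 0 cows were sampled at both days, so an effect of day or of treatment start remains untested.

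The inflammation list was higher with OA at day 4. Reads from leukocytes are argued against by PTPRC, carried by all leukocytes, which had a highest count of 0 in the 3 OA libraries, although CD14 and CD68 averaged 6.02 and 4.48 FPKM over the 12 libraries of day 4. A single cow did not set the rise, as the smallest cow median was 0.21. After thinning every library to 13509548 counts, 10 of the 10 called genes were still higher in all 3 cows. These genes had been called as higher in the same libraries, so this count decides nothing. Since only 4 of them belong to the list, all 16 members were taken too: the list median was 0.33, 0.23 and 0.23 in cows 4, 5 and 6 after thinning. The OA and CON totals of a cow differed by at most 0.06 (log2), so library size is argued against. A response of the cells to OA also stays open, with smooth muscle markers higher in the same libraries and the list losing its call with an estimated correlation (adjusted p = 0.114).

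Of 18 adipocyte markers 9, ADIPOQ among them, averaged under 1 FPKM, while others such as RBP4 (44.8 FPKM at day 4 and 69.7 at day 7) did not. Low depth is argued against by the exact 95% upper limit for ADIPOQ, 0.0217 CPM over all 24 libraries. Of these 9, 0 were without a read over all libraries and 0 reached 100 reads in any single library (LPL had 562 reads over the 12 libraries of day 4), so genes missed by the annotation or the counting stay open. No biological explanation was tested.

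Other splits of the libraries were counted for each comparison. Without the block, 10 of 10 splits of 6 libraries gave as many genes as the real 0 in each comparison of 3 against 3. The same held for 10 of 10 splits of the 6 cows in each comparison between days. The highest other was 0 throughout. Any split gives at least 0 genes, so these counts say nothing about chance. With cow as a block the real count for OA against CON at day 4 was 10 and the highest other 1, for OA against PA at day 4 30 and 2, and for OA against PA in recovered reads at day 7 8 and 0. In each of these 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Among the 3 other splits that part as many cow pairs, the highest was 0 in all 3 comparisons. For MIX against the weighted mean, 50 of 50 drawn splits gave as many as the real 0 at each day, which any split does, so this says nothing about chance. The highest other was 0 at day 4 and 1155 at day 7, where that split put 3 libraries of 1 cow into the MIX group, a count that points to a structure of the samples.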

How the results depend on the processing

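The fits on recovered reads and the alternatives to the fits with cow as a block were chosen after the data were examined. Over the comparisons, 354 values stayed within the limits set for each and 44 moved. Those that moved include the correlations of the days for PA and MIX, which changed sign with a pseudocount of 0.1. Among lists and named genes 0 results reversed. Of the list results 561 kept their side of the threshold, 337 became weaker and 64 stronger. Of the named-gene results 321 kept theirs and 399 became weaker. The median log2 difference of all genes lay between -0.00871 and 0.0174 in every comparison and setting of the 2 days. The causes below were not tested unless stated.

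Calls of 0 genes became 10 for OA against CON and 30 for OA against PA at day 4 with cow as a block. At day 7 recovered reads with the block gave 8 for OA against PA and 2 for MIX against OA, and limma without the filter gave 2 for each of PA, OA and MIX against CON. The block changed no other count.

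With the block, the 10 calls of OA against CON at day 4 became 33 by DESeq2 (5 shared), 52 without the filter (10 shared), 0 by limma and 6 with only the compared groups. Leaving out animals or libraries gave 0 to 76: without cow 4, 5 and 6 the count was 1, 0 and 76, without the CON library of cow 4 it was 0, and without the OA library of cow 4 and 5 it was 1 and 4.

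The 30 calls of OA against PA at day 4 became 59 by DESeq2 (21 shared), 117 without the filter (30 shared) and 3 by limma (1 shared). Leaving out gave 0 to 202: 9, 0 and 202 without cow 4, 5 and 6, 12, 2 and 46 without the PA library of cow 4, 5 and 6, and 12 and 3 without the OA library of cow 4 and 5.

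The 8 calls in recovered reads of OA against PA at day 7 became 53 by DESeq2 (2 shared), 210 without the filter (8 shared), 4 with the stricter filter, 17 with robust fitting (4 shared) and 0 by limma. Leaving out gave 0 to 95: 1, 25 and 3 without cow 1, 2 and 3, 0, 1 and 0 without the PA library of cow 1, 2 and 3, and 2, 33 and 95 without the OA library of cow 1, 2 and 3.

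With a pseudocount of 0.1 the correlation of the days became 0.00718 for PA and 0.00815 for MIX, from -0.0587 and -0.00678. Depth limited genes at 0 to a floor of up to 0.222 CPM.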

Other observations

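The test below was planned before its result was seen, and the leukocyte values were looked up afterwards. Among macrophage and leukocyte markers, CD14 averaged 6.02 FPKM, CD68 4.48, FCER1G 3.55 and CD163 2.38 over the 12 libraries of day 4, while PTPRC had 1 read in all of them. The entry with the highest mean FPKM at both days was the microRNA gene bta-mir-2887-2, chosen after its values were seen. It averaged 7597 ± 2271 FPKM at day 4 and 43590 ± 22440 at day 7 (SD, 12 libraries each), not tested between days. FPKM divides reads by gene length and so raises short genes, and this is not a ranking of reads.

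A hypothesis was that MIX lies between PA and OA at day 4 according to its share of OA, 40%. In each cow, 100 genes were ranked in the other cows by the difference between OA and PA, and the position of MIX was measured in the held-out cow with PA at 0 and OA at 1. The difference between OA and PA kept its sign in 75, 85 and 75 of the 100 genes in cows 4, 5 and 6. The position was 0.625, 0.373 and 0.113, with a mean of 0.371 ± 0.256 (SD, n = 3). The mean met the criterion written in advance, but a position of 0 also lay within 2 SD, so whether the mixture acts by its share of OA cannot be told apart from a position at PA.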
